A study of Mus musculus with 2 samples.

How the data were processed

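H3K9me3, trimethylation of histone H3 at lysine 9, marks silenced chromatin. In ChIP-seq, chromatin fragments that carry a mark are pulled down with an antibody and sequenced, and a peak caller lists the intervals where reads pile up. The mark was mapped in livers of mouse embryos of strain B6NCrl at embryonic day 11.5, male and female pooled, when the liver holds hepatoblasts beside many blood precursors. There were 2 biological replicates of 1 group, each with 2 technical replicates per the labels. Replicate 1 was a pool of livers from 109 embryos, and the number of embryos behind replicate 2 was not given in the sources used here.

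Each of the 4 deposited peak lists is a narrowPeak table on the mouse build mm10: a list per replicate, a list from the pooled libraries, and a replicated list. Per the file headers, replicate 1 was called from its own alignments with 2 further input files and replicate 2 from its own alignments with 1 of those. The pooled list was made from both sets of alignments with both of those files, and the replicated list from the pooled list and the replicate lists. What the further files hold was not given in the sources used here, so whether they are control libraries is unknown. The peak caller, its version, its threshold, any filter on problem regions and the rule behind the replicated list were not given in the sources used here. The fold enrichment of each peak is the authors' own ratio as their peak caller wrote it, and it was used to describe, rank or split peaks within a list. Across lists it entered the correlations and the median log2 difference over pairs of shared peaks, and within a list also the solved control count described below. The deposited p-values and q-values of each peak are −log10 values. The lowest −log10 p was 2.00 in replicate 1, 2.03 in replicate 2 and 2.05 in the pooled and replicated lists. The display score of the deposited lists was not used, and the deposited summit position entered 1 alternative. The lists hold no read counts, so the depth of each library is unknown here, no interval that needs it is given, and Wilson intervals at 95% cover only the counting error of shares of peaks.

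The lists were set against a reference of the same build (GRCm38) and its GENCODE annotation. No peak passed the end of a chromosome, and 6 peaks of each list touched a run of unknown bases. The analysis covered the 21 chromosomes (19 autosomes, X and Y), with 2647.5 Mb of ungapped sequence, 55413 annotated genes and 21938 protein-coding genes. Every interval occurred once in its list. Peaks on unplaced sequences were left out of all comparisons and are described among the additional observations.

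Replicates were compared by the share of peaks of a list that overlapped a peak of the other by at least 1 bp, and by the Jaccard index, shared base pairs over the union of base pairs. The main test was a circular shift: all intervals of a chromosome were moved by a random offset along its ungapped sequence, 10000 times, which keeps peak widths, clusters of peaks and clusters of genes. Its permutation p is two-sided, and the smallest it can give is 0.00020; for base composition, with 1000 shifts, the smallest is 0.0020. Fold enrichment of shared and unshared peaks, and correlations over pairs of shared peaks, were tested with 100000 permutations (two-sided, smallest p 1.0e-05). Peaks are not independent replicates, so these p-values describe the lists. The density of each chromosome was tested with an exact binomial test against its share of ungapped length. Peaks cluster, so those p-values are too small, and sizes in both replicates are led with.

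Each peak was placed by its midpoint in a promoter (1 kb on either side of a transcription start), coding exon, untranslated or non-coding exon, intron or intergenic sequence, in that order. A gene counted as marked when a replicated peak overlapped its body by at least 1 bp. The 17 gene lists, all tests above and the rule for named genes were fixed before the data were examined. The rule took up to 4 members per list by covered base pairs, the 10 protein-coding genes with most covered base pairs, and the 10 with the largest covered share among genes of at least 2 kb. It also took the 5 peaks of highest fold, the 5 widest peaks, the 5 domains with most covered base pairs after joining peaks within 50 kb, and the 3 unshared peaks of highest fold of each replicate. A further 15 genes were to be named whatever their values. In the erythroid list 32 of 33 fixed names matched the annotation, in the H3K9 methylation machinery list 32 of 33, and in the other lists all names matched. Benjamini-Hochberg adjustment was made over the lists, over features and over chromosomes.

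Alternatives covered stricter q-values, other definitions of overlap, lists of equal length, each replicate alone, the pooled list, other parts of the gene, other tests, and thinning of peak clusters. The uniqueness of a peak was the share of its 32-base words that occur once in the reference. The number of reads expected from the control at a peak was solved from its fold and p under a Poisson model with a pseudocount of 1, an assumption of this work. The list test was tested on simulated data: on 20 random maps of 3000 peaks, 6 of 340 list tests had p below 0.05. Those peaks were placed independently, without the clusters of the real peaks. With a peak at the middle of 60 of the 426 zinc finger genes, 60 were recovered, which that placement fixes. There 0 other lists were called. A simulated 50% of shared peaks came back as 50.1%, and 500 of 500 simulated expected counts came back within 1%. Those counts were made with the same formula, so they check the solver and not the Poisson model. They did not reach the lowest and highest counts solved here. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9.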

Results

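The data were peak lists of the histone mark H3K9me3 in mouse liver at embryonic day 11.5, from 2 biological replicates of 1 group. On the 21 chromosomes replicate 1 held 35746 peaks covering 8.73 Mb, replicate 2 held 9966 peaks covering 2.78 Mb, the pooled list 11435 peaks covering 3.51 Mb and the replicated list 7129 peaks covering 2.54 Mb. Replicate 1 thus had 3.59 times as many peaks as replicate 2. Peaks were narrow, with median widths of 210, 226.5, 241 and 279 bp in that order. Most calls were weak: 18.3% of replicate 1 peaks, 6.04% of replicate 2 peaks, 26.0% of pooled peaks and 37.9% of replicated peaks had a q-value of at most 0.05. With a single group, the design implies a comparison of the replicates with each other and of the map with the genome.

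The first comparison asked how far both pools of livers gave the same map. The replicates marked the same places far more often than shifted maps did. Some of the best covered genes carried similar lengths of peak in each while others did not. Those genes were picked by their bases under the replicated list, which was derived from the pooled list and both replicate lists. Their lengths therefore illustrate the lists and do not measure how far the replicates agree. Mroh2a, a gene of the HEAT-repeat family on chromosome 1, had 26.4 kb under replicate 1 peaks and 24.2 kb under replicate 2 peaks. Its domain had a high solved control count, given below with the best covered genes. Pcdhga1, a clustered protocadherin, had 20.0 kb and 20.2 kb, the zinc finger gene Zfp180 7.32 kb and 7.59 kb, and the imprinted gene Gnas, which encodes the alpha subunit of a stimulatory G protein, 5.72 kb and 4.55 kb. The 3 protein-coding genes with most covered bases, the long models Gm42416, Gm37013 and Gm37388 over the protocadherin cluster, had 64.7, 62.6 and 62.4 kb in replicate 1 and 42.5, 40.9 and 40.1 kb in replicate 2. Of replicate 1 peaks, 3541 (9.91%) overlapped a replicate 2 peak, against 0.228% ± 0.0366 (SD over 10000 shifts), and of replicate 2 peaks, 3512 (35.2%) overlapped a replicate 1 peak, against 0.819% ± 0.131. The Jaccard index was 8.13%, against 0.0949% ± 0.0187 after shifting. All 3 had permutation p = 0.00020, the smallest the shifts can give. Both replicates were called with 1 common input file, and shifted maps do not show how much overlap that file alone could give.

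Shared peaks were the stronger ones within each list. In replicate 1 the median fold enrichment was 3.53 at shared and 3.21 at unshared peaks (permutation p = 1.0e-05, the smallest possible), and in replicate 2 it was 3.30 and 3.10 (permutation p = 6.0e-05). The shared part was larger among the strongest calls by −log10 p than among the weakest: it went from 4.98% (Wilson 95% interval 4.31 to 5.74) in the weakest 10% of replicate 1 to 32.3% (30.7 to 33.8) in its strongest 10%, and from 24.6% (22.0 to 27.3) to 74.0% (71.2 to 76.6) in replicate 2, where many weak peaks had the same −log10 p of 2.75 and the lowest share, 20.9%, was not in the weakest 10%. Over the 3541 pairs of shared peaks, across peaks, folds correlated with a Spearman rho of 0.225 and a Pearson r of 0.306 on the log2 scale (permutation p = 1.0e-05 for both). If it is a control, the common input file could by itself make folds correlate, and the permutations do not allow for it. The 3 strongest unshared peaks of replicate 1, all of fold 6.42, lay on chromosome 9 at 3158485–3158883 and 13891622–13892442 and on chromosome 7 at 10209609–10210080, outside protein-coding genes. Those of replicate 2 lay in 3300002I08Rik and Gm10130 (chromosome 2, 150346382–150346704, fold 5.75), in Col13a1 (chromosome 10, 61863587–61863923, fold 5.55) and 971 bp from Rpf2 (chromosome 10, 40221490–40222274, fold 5.35). Each of these 6 peaks lay on a peak of the replicated list.

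**Figure D1:**
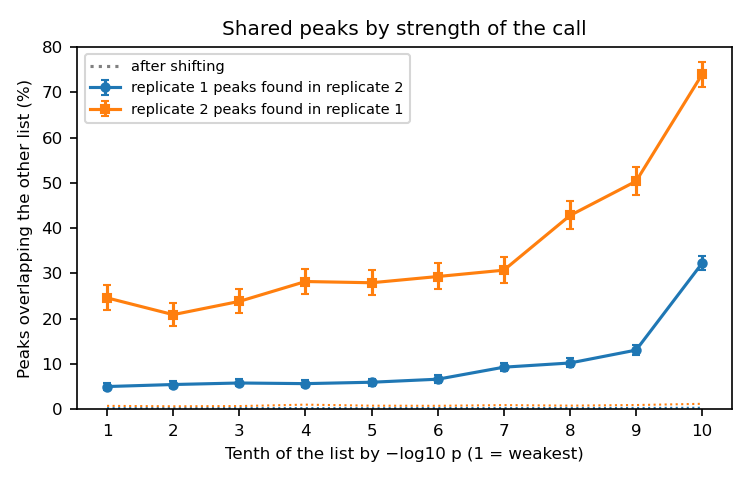
Percent of peaks of each replicate that overlap a peak of the other, in steps of 10% of the list ordered by −log10 p; bars are Wilson 95% intervals and dotted lines the mean after shifting. The share in the strongest 10% was 32.3% for replicate 1 and 74.0% for replicate 2, and no shifted mean passed 1.16%.

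Every replicated peak was an interval of the pooled list, but overlap with both replicate lists was not a condition. Of the 7129 replicated peaks, 3187 (44.7%) overlapped a peak of both replicates, 2173 (30.5%) of replicate 1 alone, 1213 (17.0%) of replicate 2 alone and 556 (7.80%) of neither. The replicated list was used below as deposited.

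The second comparison asked where in the genome the mark lay. Replicated peaks were most dense on chromosome 7, with 7.23 peaks per Mb, on chromosome 17 with 5.56, on chromosome 5 with 4.63 and on chromosome 4 with 3.46, against 2.69 over the genome. They were sparse on chromosome 14 (1.26 per Mb), chromosome X (0.563) and chromosome Y (0.0681), in pools of both sexes. Chromosome 7 held 14.4% of the peaks on 5.36% of the ungapped length, a ratio of 2.69, with ratios of 1.86 in replicate 1 and 2.29 in replicate 2. By exact binomial tests 7 chromosomes (4, 5, 7, 9, 13, 17 and 18) lay above the genome and 11 below, and chromosomes 8, 10 and 19 were not past the threshold. Of the 18 called chromosomes, 17 lay on the same side in both replicates, and chromosome 13 had a ratio of 1.13 in the replicated list and 0.927 in replicate 1. In replicate 1 alone chromosomes 8 (ratio 1.31), 10 (1.19) and 19 (0.917) passed the threshold and chromosomes 3, 4 (1.04), 15 and 16 did not. In replicate 2 alone chromosome 10 (1.19) passed and chromosomes 9 (1.08), 12 and 13 did not. With 1 peak kept per 50 kb domain, chosen after the values were seen, 5 chromosomes lay above and 3 below.

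**Figure D2:**
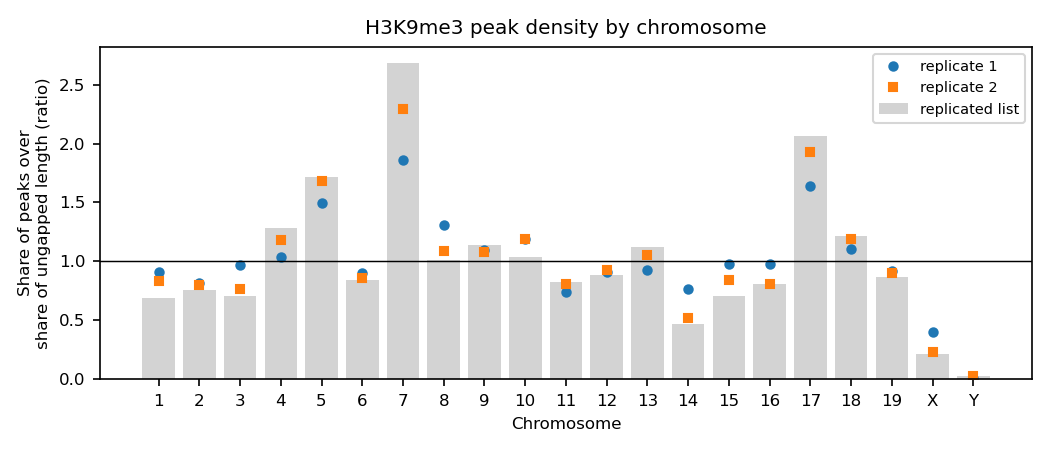
Share of peaks on each chromosome over its share of ungapped length (ratio, y axis; the line marks 1), for the replicated list (bars) and both replicates (points). Chromosomes 7 and 17 stood at 2.69 and 2.07, chromosome X at 0.209.

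The mark was over-represented in coding exons. Midpoints of 312 replicated peaks (4.38%) lay in coding exons, against 1.05% ± 0.144 (SD over shifts), a ratio of 4.15, and the ratio was 1.70 in replicate 1 and 3.32 in replicate 2. Zinc finger genes held 144 of these peaks and clustered protocadherins 35. The zinc finger genes were here the listed genes and any others coding for 5 or more finger motifs. Outside those classes, a split chosen after the values were seen, 2.02% of peaks lay in coding exons against 1.05% (ratio 1.92, permutation p = 0.00020). Introns held fewer peaks than shifted maps, 31.5% against 40.1% (ratio 0.784; 0.774 in replicate 1 and 0.773 in replicate 2). Coding exons and introns each had an adjusted permutation p of 0.00025 in the replicated list and in replicate 2 and of 0.00033 in replicate 1.

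Promoters held 9.48% of replicated peaks against 6.65% (ratio 1.43), and untranslated or non-coding exons 4.00% against 2.48% (ratio 1.61), both with an adjusted permutation p of 0.00025. Neither excess was seen in replicate 1 alone, where the ratios were 0.995 (adjusted permutation p = 0.90) and 0.922 (adjusted permutation p = 0.091), while replicate 2 gave 1.29 and 1.41. With promoters of protein-coding genes alone the promoter ratio was 1.15 and missed the threshold (adjusted permutation p = 0.13). Intergenic sequence held 50.7% of replicated peaks against 49.7% (permutation p = 0.56), but lay above shifted maps in replicate 1 (58.8% against 50.2%, adjusted permutation p = 0.00033) and in replicate 2 (53.7% against 49.8%, adjusted permutation p = 0.0060). Peaks were richer in G+C than shifted intervals (median 46.8% against 42.0%) and held less soft-masked sequence, which stands for repeats (17.1% against 22.7%), both with permutation p = 0.0020, the smallest possible there. Shifts also move peaks onto sequence where reads cannot be placed with certainty, and the uniqueness of shifted intervals was not computed. Of the replicated peaks, 88.8% had 90% or more unique words. The lower share of soft-masked bases therefore does not show that the mark avoids repeats. The same limit applies to the feature shares and to the density per ungapped Mb.

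Among the 17 gene lists, zinc finger, imprinted and clustered protocadherin genes carried more peaks than shifted maps gave. Zinc finger genes, many of which encode repressors that bind transposable elements, were marked in 119 of 426 cases (27.9%), against 26.4 ± 7.02 genes, 4.50 times as many (adjusted permutation p = 0.0017). Replicate 1 marked 170 of them against 99.7 (ratio 1.71) and replicate 2 124 against 35.9 (ratio 3.46). The leading members were Zfp180 (chromosome 7, 24081924–24107713), with 7 peaks over 7.89 kb or 30.6% of its body, Zfp873 (chromosome 10, 82048123–82064745) with 12 peaks over 7.61 kb or 45.8%, Zfp930 (chromosome 8, 69209038–69230536) with 15 peaks over 7.30 kb, and Zfp110 (chromosome 7, 12834761–12850577) with 13 peaks over 6.68 kb. The excess passed the threshold over gene bodies but not at start sites. Within 1 kb of the start site 8 zinc finger genes had a peak against 3.53 (ratio 2.26, adjusted permutation p = 0.50). Zfp180 and Zfp110 were among them, and with so few genes an excess at start sites cannot be excluded. Over all alternatives of this list, Fisher's exact test included, the adjusted p ran from 1.3e-40 to 0.50.

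Imprinted genes, expressed from the copy of a single parent, were marked in 28 of 62 cases (45.2%), against 6.37 ± 2.63, 4.39 times as many (adjusted permutation p = 0.0017). Replicate 1 marked 41 against 21.03 and replicate 2 23 against 8.60. Gnas (chromosome 2, 174284320–174346744) had 10 peaks over 5.83 kb, Peg3 (chromosome 7, 6703892–6730431) 4 peaks over 3.13 kb, Mest (chromosome 6, 30723547–30748465) 4 peaks over 2.42 kb, and Kcnq1 (chromosome 7, 143106362–143427042) 5 peaks over 2.18 kb. To within 1 kb of the Peg3 start site reached 3 peaks, the farthest upstream of them outside the gene body. All 5 of the Kcnq1 peaks lay in the antisense transcript Kcnq1ot1 within it. Cdkn1c, a cell-cycle inhibitor expressed from the maternal copy, had 77.6% of its 2.71 kb body covered by 2 peaks, with 43.1% covered in replicate 1 and 57.9% in replicate 2. The H19 body (chromosome 7, 142575529–142578143) held no peak of any list, though a replicate 1 peak lay within 1 kb of its start site. The annotated control region of H19 and Igf2 (chromosome 7, 142580248–142582833), looked at after the values were seen, held 2 replicated peaks over 0.995 kb, with 1.02 kb in replicate 1 and 0.187 kb in replicate 2.

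Clustered protocadherin genes, which encode neuronal cell-surface proteins, were marked in 42 of 57 cases (73.7%), against 6.57 ± 9.0, 6.39 times as many (adjusted permutation p = 0.024). Replicate 1 marked 54 of them against 24.7 (ratio 2.19) and replicate 2 46 against 9.99 (ratio 4.61). Pcdhga1 (chromosome 18, 37661793–37841873) had 47 peaks over 21.7 kb, Pcdhga2 46 peaks over 21.4 kb, Pcdhga3 45 peaks over 20.99 kb and Pcdhgb1 42 peaks over 20.1 kb. These genes are nested and share their last exons, so a peak can count for several. Counted as blocks of neighbouring genes, an alternative chosen after the values were seen, 3 of 3 blocks were marked against 0.788 (adjusted permutation p = 0.21), and with 1 peak per 50 kb domain the ratio was 0.327.

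**Figure D3:**
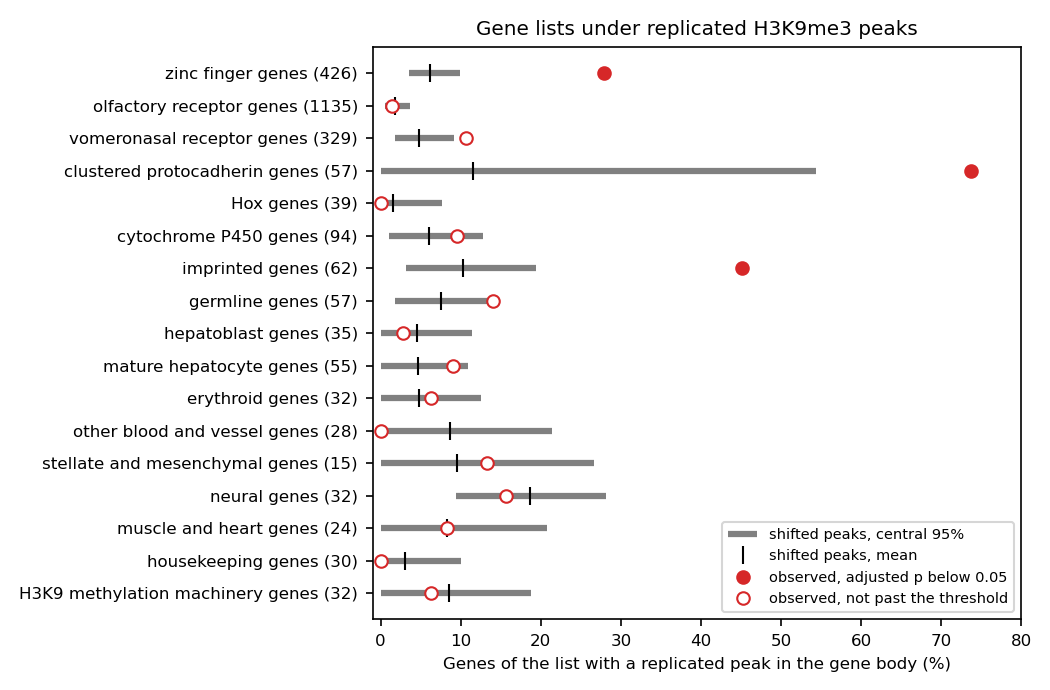
Percent of genes of each list (number of genes in brackets) with a replicated peak in the gene body, beside the mean and central 95% of 10000 shifted maps. Filled points mark the zinc finger, clustered protocadherin and imprinted lists, at 27.9%, 73.7% and 45.2%.

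Germline genes were marked at start sites. Within 1 kb of the start site 6 of 57 had a replicated peak, against 0.312, 19.2 times as many (adjusted permutation p = 0.0011; over all alternatives of this list, Fisher's exact test included, the adjusted p ran from 0.0011 to 1). The 6 were Dazl and Ddx4, an RNA-binding protein and a helicase of germ cells, Mael, Sycp1 of the synaptonemal complex, Rhox13 and Taf7l. Dazl, Ddx4, Rhox13 and Taf7l had a start-site peak in both replicate lists, and Mael and Sycp1 in replicate 2 but not in replicate 1. Taf7l (chromosome X, 134460118–134476490) had 1 replicated peak over 0.754 kb, Ddx4 (chromosome 13, 112598333–112652475) 0.668 kb, Dazl (chromosome 17, 50279395–50293636) 0.564 kb, and Meioc (chromosome 11, 102663716–102682237) 0.534 kb away from its start. Over gene bodies 8 of 57 were marked against 4.29 (adjusted permutation p = 0.38). Start sites were also marked in 26 clustered protocadherin genes against 0.348 (ratio 74.7) and in 14 imprinted genes against 0.506 (ratio 27.7). Each of these 2 lists had an adjusted permutation p of 0.0011 there. Mael, Sycp1 and Rhox13 were named after their values were seen.

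Vomeronasal receptor genes missed the threshold, with 35 of 329 marked against 15.98 ± 6.13 (ratio 2.19, adjusted permutation p = 0.060), and passed it in replicate 2 (ratio 2.11, adjusted permutation p = 0.029) and in the pooled list (ratio 2.25, adjusted permutation p = 0.0093) but not in replicate 1 (ratio 1.35, adjusted permutation p = 0.16). Vmn2r60, with 4 peaks over 1.14 kb, Vmn1r69 with 1.03 kb, Vmn2r53 with 0.910 kb and Vmn2r59 with 0.814 kb led that list, all on chromosome 7. Olfactory receptor genes were marked in 16 of 1135 cases against 20.5 ± 8.96 (ratio 0.780, adjusted permutation p = 1.0), while replicate 1 gave a ratio of 1.45 (adjusted permutation p = 0.14) and replicate 2 a ratio of 1.12 (adjusted permutation p = 0.99). That list was led by Olfr398 (1.04 kb), Olfr394 (0.447 kb), Olfr137 (0.416 kb) and Olfr1491 (0.321 kb). Cytochrome P450 genes were marked in 9 of 94 cases against 5.71 (adjusted permutation p = 0.69), led by Cyp3a11 (1.24 kb), Cyp3a16 (0.781 kb), Cyp2c29 (0.562 kb) and Cyp2c66 (0.494 kb), and 0 of 39 Hox genes were marked against 0.584 (adjusted permutation p = 1.0).

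Few hepatoblast, erythroid and other blood and vessel genes carried replicated peaks. Their lists are short, the shifted maps gave few there too, and expression was not measured here. Albumin (Alb), alpha-fetoprotein (Afp), transthyretin (Ttr) and the hepatocyte regulator Hnf4a, as well as the erythroid regulator Gata1 and the globin genes Hbb-bs and Hba-a1, held no peak in any list. Of the hepatoblast list 1 of 35 genes was marked, Nr5a2 (0.30 kb), against 1.61. Of the erythroid list 2 of 32 were marked, Sptb (0.724 kb) and Zfpm1 (0.537 kb), against 1.53, and of other blood and vessel genes 0 of 28 against 2.42 (adjusted permutation p = 0.40). None of these lists passed the threshold in the replicated list. In replicate 1, other blood and vessel genes did, with 3 marked against 8.91 (ratio 0.337, adjusted permutation p = 0.026). Replicate 2 gave 1 against 3.36 (adjusted permutation p = 0.59). Hepatoblast genes were marked in 4 cases in replicate 1 against 7.22 and in 0 in replicate 2 against 2.37. Erythroid genes were marked in 4 cases in replicate 1 against 6.56 and in 2 in replicate 2 against 2.14. Neither of the latter lists passed the threshold in either replicate.

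The remaining lists also stayed within the shifted range. Mature hepatocyte genes were marked in 5 of 55 cases against 2.57 (adjusted permutation p = 0.55): Ugt1a1, the enzyme that conjugates bilirubin (6.02 kb), Cyp3a11 (1.24 kb), the urea-cycle genes Ass1 (0.766 kb) and Asl (0.115 kb), and Cyp2c29 (0.562 kb). Asl was named after its value was seen. Ugt1a1 lies in the same domain of high solved control count as Mroh2a. Neural genes were marked in 5 of 32 cases against 5.97, led by Slc17a7 (1.14 kb), Grin2b (0.717 kb), Syt1 (0.567 kb) and Nrxn1 (0.330 kb). Muscle and heart genes were marked in 2 of 24 cases against 1.99, namely the titin gene Ttn, with 14 peaks over 4.42 kb, and Ryr1 (0.585 kb). Stellate and mesenchymal genes were marked in 2 of 15 cases against 1.44, namely Pdgfrb (0.409 kb) and Reln (0.254 kb). Housekeeping genes were marked in 0 of 30 cases against 0.908, with no peak of any list in Actb or Gapdh. Of the H3K9 methylation machinery, 2 of 32 genes were marked against 2.72, Atf7ip (1.27 kb) and Resf1 (0.677 kb), while Setdb1, Suv39h1 and Zfp57 held no peak in any list. Adjusted p was 1.0 for these 5 lists. Over all 21938 protein-coding genes 1499 (6.83%) were marked in the replicated list, against 1497 (permutation p = 0.97). Each replicate alone marked fewer than shifted maps, 4163 against 5559 in replicate 1 (ratio 0.749) and 1839 against 2082 in replicate 2 (ratio 0.883), both with permutation p = 0.00020.

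The widest coverage of single genes lay in a few clusters. Mroh2a (chromosome 1, 88226986–88262289) had 17 peaks over 28.9 kb, 81.9% of its body, and beyond Hjurp the cold-sensing ion channel gene Trpm8 had 25 peaks over 20.5 kb. Both genes and Ugt1a1 lie in a domain where the solved control count was high, with a median of 13.1 against 2.37 over all replicated peaks. The median fold there was 2.86 against 3.41, and this domain is taken up again among the additional observations. Gm42416, Gm37013 and Gm37388, long gene models that run across the protocadherin cluster, held 47.9, 45.5 and 45.3 kb, and Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 and Pcdhga4 held between 21.7 and 19.5 kb. By covered share, Ugt1a1 (85.5%) led, followed by Mroh2a, Cdkn1c, Asmt (77.5%), which makes melatonin, the cytokine receptor gene Il3ra (68.8%), Zfp146 (68.7%), Klf14 (67.7%), Gm21738 (55.1%), the cytokine receptor gene Crlf2 (47.0%) and Zfp873. In each replicate alone, Ugt1a1 was covered over 83.9% and 73.6% and Asmt over 71.1% and 77.2%, while Klf14 was covered over 20.0% in replicate 1 and 43.4% in replicate 2.

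**Figure D4:**
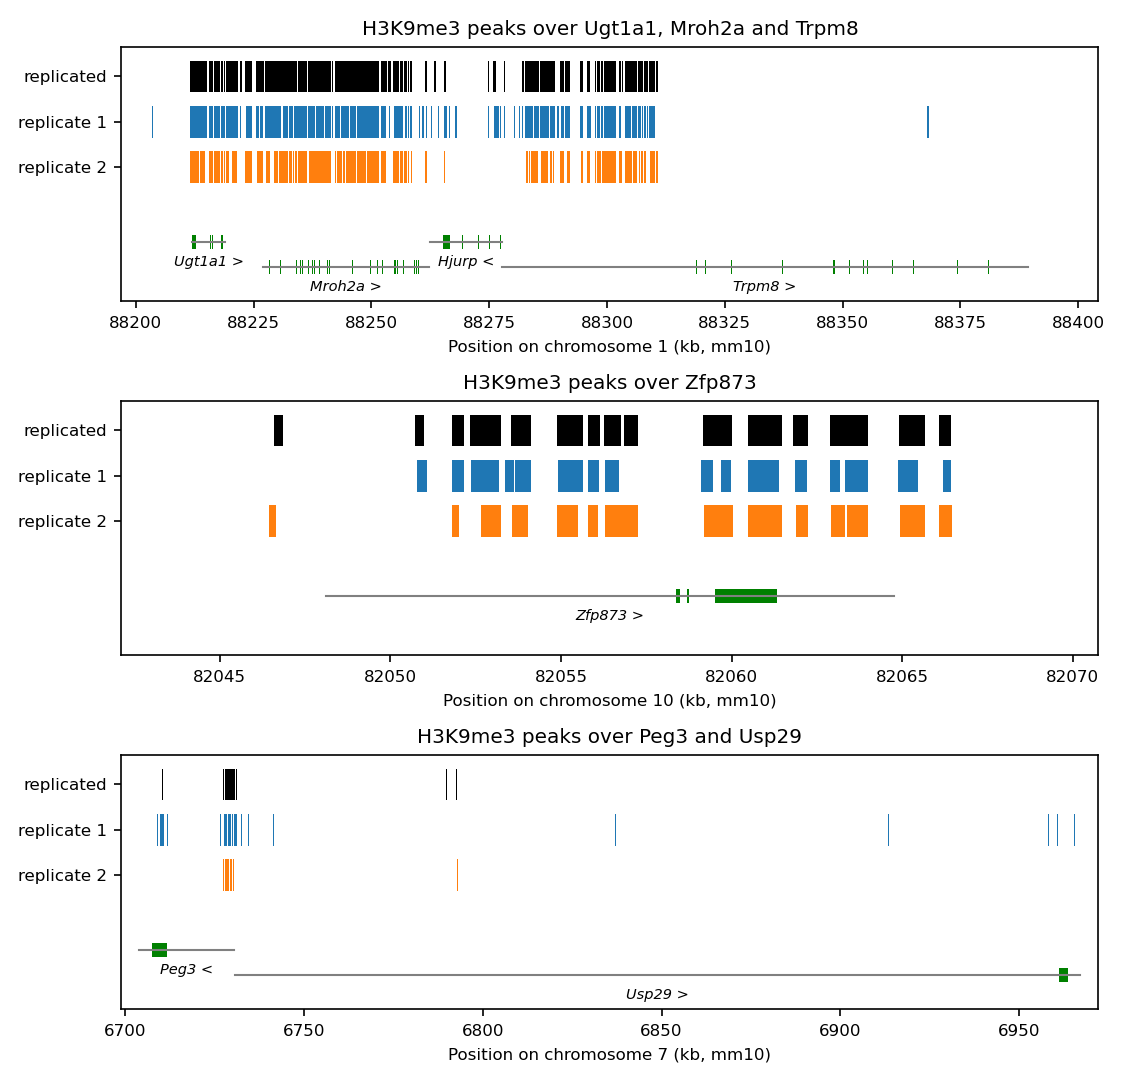
Peaks of the replicated list and of both replicates (blocks, to scale) over coding exons (green) of Ugt1a1, Mroh2a, Hjurp and Trpm8 on chromosome 1, Zfp873 on chromosome 10, and Peg3 and Usp29 on chromosome 7; x axes in kb. Replicated peaks cover 81.9% of Mroh2a and 45.8% of Zfp873, and 3 peaks reach within 1 kb of the Peg3 start site.

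Joined within 50 kb, the replicated peaks formed 3548 domains, of which 71.7% were a single peak, and the 50 largest held 26.1% of the covered base pairs. The domain with most covered bases ran over the Ugt1a genes, Mroh2a, Hjurp and Trpm8 on chromosome 1 (88211442–88310835), with 55 peaks over 63.4 kb, 61.4 kb in replicate 1 and 50.4 kb in replicate 2. Next were the protocadherin beta and gamma clusters (chromosome 18, 37249285–37767768; 105 peaks, 41.1 kb), the start of chromosome 3 (3000056–3333511; 47 peaks, 30.7 kb), Ceacam genes on chromosome 7 (17595572–18226362; 93 peaks, 30.0 kb) and secretoglobin genes on chromosome 7 (33575385–34027796; 80 peaks, 27.3 kb). In replicates 1 and 2 these 4 domains held 51.4 and 36.3 kb, 36.4 and 20.2 kb, 58.3 and 24.5 kb, and 40.6 and 24.3 kb in that order. The widest peak, 7257 bp, lay in Mroh2a (chromosome 1, 88244463–88251719). The others of the 5 widest lay at 88236595–88241416 in the same gene, on chromosome 4 at 3049939–3055327 and 3080266–3084893, and on chromosome 13 at 119612880–119617696, 1.82 kb from Tmem267.

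The peak of highest fold, 11.8, lay on chromosome Y at 258991–259471, 465.7 kb from Zfy1, where 36.9% of its 32-base words were unique in the reference. It was followed by a peak in Zfp981 (chromosome 4, 146535915–146536594, fold 9.85), peaks in Gm21887 (chromosome X, 170010579–170011620, fold 8.18, and 170008961–170010033, fold 8.04), with 0% of unique words, and a peak in Gm45844 (chromosome 7, 7277902–7278245, fold 8.03, 49.8% unique). All 5 overlapped peaks of both replicates. Reads of sequence that is not unique cannot be placed with certainty, so these positions are uncertain where the unique share is low.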

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

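The tests of the expected count at the peaks of smallest p, and of extra copies at Mroh2a and Trpm8, were chosen only after the result was seen. Of the full replicated list, 237 peaks (3.22%) lay on 21 sequences outside the 21 chromosomes, above the 0.0407% that a count of 0 would allow. They drew attention because the comparisons left this part of the data out. Their median fold was 3.69 against 3.41 on the chromosomes, 75.9% had a q-value of at most 0.01, and they covered 162 kb.

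Replicate 1 held 3.59 times as many peaks as replicate 2, and few of them overlapped. Weak calls near the peak threshold may account for part of this. The weakest 10% of replicate 1 by p was found in replicate 2 at 0.154 times the share of the strongest 10%. Opposite ends of the Wilson intervals of both shares gave 0.128 to 0.187. A deeper library or control behind replicate 1 stays open. At 75.5% (74.0 to 76.9) of shared peaks, 2673 of 3541, −log10 p was higher in replicate 1, with medians of 4.86 and 3.51. Folds differed by a median of 0.0096 on the log2 scale. The bound set for that explanation lies inside the interval of the 75.5%. The median solved control count was 2.11 in replicate 1 and 1.12 in replicate 2, and 11.1 and 6.28 over the domain of Mroh2a. These counts go with that explanation, but they rest on the Poisson model and on different sets of peaks. The pooled list, made from both sets of alignments with both input files, held 11435 peaks against 35746 in replicate 1. Depth alone would give the pooled list at least as many, so these values argue against depth as the only cause. That holds only if the lists share a threshold, which was not given. The file headers list 2 further inputs for replicate 1 and 1 of those for replicate 2. No biological explanation was tested, since the replicates belong to 1 group.

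The 50 replicated peaks of smallest p lay in 28 windows, with a median fold of 5.16 against 3.41 for the others. The largest were a window at Sfi1 and Drg1 (chromosome 11, 3184217–3200107), with 7 of the 50 peaks and a median solved control count of 80.9, and Gm21887 and Mid1 on chromosome X with 6. Many background reads at these windows may contribute, since the solved count of the 50 was 4.94 (3.30 to 5.98) times that of the others, although part of this is built in because p falls with the count at a given fold. Sequence repeated elsewhere in the reference was not settled, with a median of 89.5% (80.8 to 94.0) unique words, 10 of the 50 peaks under 50% and 23 at 90% or more. The Ugt1a genes, Mroh2a, Hjurp and Trpm8 lie in a single domain, where the median peak was 100% unique. There the solved count was 5.51 (5.22 to 6.02) times that of the other peaks. Extra copies in these animals of sequence that the reference holds once could give this. The other 4 large domains stood at 0.991 to 1.0 times all replicated peaks, and no biological explanation was tested. The intervals in this paragraph are bootstraps over peaks, and for ratios the median of the other peaks was held fixed. They are too narrow, since neighbouring peaks of a window or domain are not independent.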

How the results depend on the processing

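Chosen only after the results were seen were the alternatives that kept replicated peaks overlapping both replicate lists, peaks of 90% or more unique words or a q-value of at most 0.05, blocks of genes, and thinned chromosomes. No paired analysis was possible because there was 1 group. Of 348 alternatives to the results that answer a comparison, 313 counted as unchanged, and of 519 for named genes and chromosomes 307 did, with 185 covered lengths of named genes moved by more than the SD between replicates. Tested values counted as unchanged if direction and side of the threshold stayed. A direction counted as turned only where a value past its threshold was involved, so olfactory genes at 0.780 and 1.45 counted as unchanged. Counts and covered lengths of lists counted as unchanged within a ratio of 1.5, and shares of replicated peaks within a Wilson interval. The 313 include taking every row of a list, which changes nothing because no interval was repeated. The overlap of the replicates exceeded the shifted value under every alternative run (100 shifts where overlap by 50% was required), with 5.61% to 23.5% of replicate 1 and 19.6% to 85.5% of replicate 2 shared. The imprinted list passed in all 14 alternatives, zinc finger genes in 13 and clustered protocadherins in 12.

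At a q-value of at most 0.01, peaks numbered 2911 in replicate 1, 333 in replicate 2, 1669 pooled and 1599 replicated, covering 1.10, 0.244, 0.900 and 0.884 Mb; at 0.001 they numbered 833, 168, 695 and 690, covering 0.449, 0.158, 0.518 and 0.516 Mb, by construction of a stricter threshold. With 50% of either interval required, 73.8% of replicated peaks were found in replicate 1. With 1 peak per 50 kb domain, 3 chromosomes lay below the genome, the ratios of chromosomes 6, 11 and 16 turned to 1.11, 1.02 and 1.01 and that of chromosome 18 to 0.964, and protocadherins fell to 0.327, since their cluster then holds few peaks. Protocadherins as blocks gave 3.81, with 3 blocks to test. Without replicate 1 or replicate 2, chromosome 13 ran from 0.927 to 1.05, promoters from 0.995 to 1.29, untranslated or non-coding exons from 0.922 to 1.41, intergenic sequence from 1.08 to 1.17 (past the threshold in both), vomeronasal genes from 1.35 to 2.11 and other blood and vessel genes from 0.298 to 0.337. Promoters of protein-coding genes alone gave 1.15 and missed the threshold. At start sites zinc finger genes gave 2.26 and missed it, and germline genes gave 19.2 and passed it. Vomeronasal genes passed it without replicate 1, with the pooled list (2.25), with 5 kb on either side (2.20), by Fisher's exact test (1.57) and against lists matched on length (2.66), but not under the others, such as a q-value of at most 0.01 (1.49) or 0.001 (0.670), with peaks in both replicate lists (1.86), as blocks (1.57) and with 1 peak per 50 kb domain (0.515). Fisher's exact test, which ignores gene length and clusters, called 5 lists in place of 3, with olfactory genes at 0.198, while the pooled list gave them 1.30, 5 kb on either side 1.45 and blocks 1.48, none past the threshold. For changes with no reason given here the cause was not tested. Depth is unknown in these lists, so genes without peaks are unmarked only at the authors' threshold.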

Other observations

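The tests of finger classes outside the zinc finger list, of chromosome starts and of symbol families were chosen only after the result was seen. Genes outside the zinc finger list whose coding sequence holds 5 or more C2H2 finger motifs were also marked beyond shifted maps, in 28 of 162 cases against 12.04 ± 3.348 (ratio 2.33, adjusted permutation p = 0.00060). Examples were AU041133 (chromosome 10, 82128013–82153065), with 14 motifs and 15 peaks over 6.50 kb, 2610008E11Rik with 14 motifs and 4.37 kb, Gm4924 with 18 motifs and 3.28 kb, and Rbak with 14 motifs and 1.34 kb. In both groups together, genes with 10 or more motifs were marked in 106 of 308 cases (ratio 5.25), genes with 5 to 9 in 32 of 201 (ratio 2.45) and genes with 1 to 4 in 35 of 294 (ratio 1.27, adjusted permutation p = 0.16).

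Zinc finger genes carried 4.50 times as many marked members as shifted maps gave. Reads shared between copies with identical 32-base words do not account for it alone, since the ratio was 4.32 with only peaks of 90% or more unique words. Copies that differ within each word, or that the reference lacks, count as unique here, so reads shared between those cannot be excluded. A few dense clusters of peaks do not account for it alone either, since the ratio was 3.97 with 1 peak per 50 kb domain. Both ratios stayed past the threshold. A hypothesis is that the mark may lie over the sequence that codes for the fingers. In the 118 zinc finger genes with a finger and a replicated peak, 47.1% of the 91.7 kb of finger-coding bases were covered against 3.82% of the other gene bases, 12.3 times as much, and rotating the covered blocks within the genes 10000 times gave 9.08% (permutation p = 0.00020, the smallest possible). That test was set before its result was seen, but on the genes that carry the pattern, so it does not show what places the mark. The rotation also moves covered blocks onto sequence where reads cannot be placed with certainty. Part of the contrast may therefore reflect where peaks can be called, which was not tested.

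The first 1 Mb of ungapped sequence of the 19 autosomes held 258 replicated peaks against 55.5 in shifted maps (ratio 4.65, permutation p = 0.00020), with peaks on 17 of the 19 autosomes. The first 5 Mb, which contain that first 1 Mb, held 471 replicated peaks against 279 (ratio 1.69, permutation p = 0.043). The ratio was 1.45 in replicate 1 (permutation p = 0.014), 1.38 in replicate 2 (permutation p = 0.14) and 1.49 in the pooled list (permutation p = 0.096). Sequence beyond the first 1 Mb was not tested on its own, so these ratios do not show that the excess reaches past it. In the first 1 Mb, chromosome 3 held 51 of the replicated peaks, and 207 remained without it. No filter on uniqueness or background was applied there. That sequence includes the window at Sfi1 and Drg1 on chromosome 11, with a median solved control count of 80.9. Replicate 1 gave a ratio of 2.46 (permutation p = 0.00020) and replicate 2 a ratio of 3.53 (permutation p = 0.00060). Of 263 gene families sharing a symbol stem, with 10 genes or more, 0 passed the threshold of the shift test after adjustment and 7 had an unadjusted p below 0.05. Secretoglobin genes (Scgb) came closest, with 8 of 34 marked against 0.469 (adjusted permutation p = 0.053). Ceacam genes were marked in 6 of 15 cases against 0.867 and Nlrp genes in 7 of 17 against 2.01 (adjusted permutation p = 0.91 and 1.0).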
